A study of Homo sapiens with 8 samples.

How the data were processed

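ATAC-seq libraries were made from 8 fractions of crosslinked, permeabilised and tagmented 293T cells, the flow-through of a Q Sepharose incubation (FT) and 7 successive NaCl washes (G20 to G1000, named by the mM of NaCl), per the labels' protocols. Each fraction was 1 library. The libraries of neighbouring washes came from the same column, as far as the labels tell, and are not replicates of each other.

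Reads were processed with Bowtie2 2.2.6, MACS2 2.2.1 and HOMER, per the submitters' processing notes, which give no HOMER version and list the builds hg19 and mm10. The chromosome names and scaffold names in the files were those of hg19, and coordinates are given in that build, counted from 1. Read filters, the handling of reads that map to several places, any shift of reads for the transposase and the peak calling parameters are not given in the sources used here. Multiply mapped reads matter for the satellite and ribosomal DNA regions below. The authors called peaks for each library alone. Each peak list deposited by the authors holds an integer score, a fold enrichment (a ratio of summit pileup to background), and the −log10 p and −log10 q of the peak, with its interval and summit. The smallest −log10 q was 1.30 to 1.32 in each list, and 0 intervals were repeated. These folds and −log10 values are the authors', and were used to rank, filter and describe peaks within a list.

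Within the files, peaks of the FT list are named GL and those of the G200 list G50_200. In the G200 list 13.6% of the fold enrichments have fewer than 5 decimals, against 0% in each of the other 7 lists. The groups follow the labels' titles, and what the different names and number format mean was not settled. Whether the G200 list is that of the 200 mM wash, of a pooled fraction or of another run could not be read from the sources used here.

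Depth is not listed in a peak file, so it was recovered. MACS2 computes the fold as the pileup plus 1 over the background plus 1, and the p-value from a Poisson distribution with that background. Both equations were solved for a whole-number pileup, up to 3000, with a match within 0.001 of the printed −log10 p. A match was found for between 99.98% (G100) and 100% of the peaks of a list, against 0.488% to 0.765% after the p-values had been shuffled among the peaks. A single pileup was kept for between 99.3% (G500) and 100% (G300) of the peaks. Pileups are called reads here, although for paired reads they may be fragments. The lowest background value of a list was shared by between 52 peaks (G700) and 1173 peaks (G300), and it was taken as the genome background. Other background values were multiples of a step that corresponds to an extension length of 260.0 bp (G20) to 293 bp (G200). Between 99.4% and 100% of them lay within 0.0005 of a multiple, where 6.82% to 7.69% would by chance. The genome background over the extension length gave the background reads per kb, from 0.817 in G200 to 2.36 in FT, which is a relative depth and not a read total. It can be compared between lists only if their peak calling settings were alike.

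Peaks of the 8 lists that shared at least 1 bp were merged into regions. Pairs of lists were compared by the Jaccard index of covered bases and by the share of overlapping peaks, with 20 seeded shuffles of the peaks within chromosomes as background. Because a longer list overlaps more by itself, each comparison was repeated with the 8102 peaks of highest −log10 q of each list, the length of the shortest list. The lowest −log10 q kept was then 7.89 in FT, 7.18 in G20, 6.95 in G300 and 1.32 in G700. In the other lists it was 3.23 to 5.36. Lists of equal length were therefore not equally strict. Trends over the 7 salt libraries were tested with exact permutation tests of Spearman's rho and Pearson's r (5040 orders, two-sided), with Benjamini-Hochberg adjustment over the 30 trends. Low-side regions were called in FT, G20 and G100 and in none of G500, G700 and G1000, and high-side regions the reverse. The permutation test of peak width, the split into sides, the named regions and part of the alternatives were fixed before the data were examined. The other trends, the test of list similarity against salt distance and the Fisher's exact tests by chromosome were not part of that plan. The named regions are the 2 peaks of highest −log10 q per list, the 12 low-side and high-side regions and the 10 regions of all lists with the highest mean rank. Other named regions were chosen after their values were seen.

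The comparison of recovered reads was added after the data were seen. For each region called in all 8 lists with a recovered pileup in each, the highest pileup per library was tested against the other 7 libraries with an exact binomial test (two-sided, 33760 tests, Benjamini-Hochberg adjusted), with expected shares from the ordinary regions. The summed reads of the low side and the high side were tested in the same way. Intervals of read ratios are 95% Poisson intervals and those of shares are 95% Clopper-Pearson intervals, and both cover counting error only. The regions were selected by being called in each list, which bounds their reads from below. The longest peak-free stretch of each chromosome was found from the merged regions, and regions within 1 Mb of it, within 20 kb of a chromosome end, or on unplaced sequences were kept out of the ordinary set. These classes rest on position alone, with no annotation of centromeres or repeats. The ordinary set therefore still holds regions such as chromosome 1 from 566064 to 566755 and chromosome 21 from 9826754 to 9827559. Nothing ties the stretch of each chromosome to its centromere. On chromosome X it ran from 141237973 to 146993069. The chromosome X region from 61691396 to 61692174 stayed ordinary, with 0.368 times the expected reads in G200. On simulated data, 99.9% of 7979 pileups were recovered and 0 were wrong, and 100% of 2000 planted regions were merged as planted. In 4220 simulated regions, 45.5% of 200 regions raised 2 times in 1 library were called and 97.5% of 200 raised 3 times, with 8 and 9 unchanged regions called. With no change simulated, 0 were called.

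Alternatives were a stricter −log10 q of at least 5, equal list length, leaving out chromosome Y and unplaced sequences, a reciprocal overlap of at least 50%, summits within 100 bp, windows of 200 bp around summits, calls in at least 2 of 3 lists, FT added to the salt order of peak width, and each library left out for peak width and for the low-side and high-side regions. Added after the data were seen were FT in the salt order of list similarity, each library left out of the count of shared regions and of all counts from recovered reads, another scaling, ordinary regions alone, regions with 1 peak in each list, reads by chromosome without the regions whose reads differed, and leaving out FT and G200 together. Promoter share, GC content, motifs and gene lists had been planned and were not analysed here, because no hg19 genome or annotation was used here. Regions are therefore named by position and not by gene. Analyses were run in Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.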

Results

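Open chromatin was profiled by ATAC-seq in 293T cells, a human embryonic kidney line that carries the SV40 large T antigen. ATAC-seq uses a transposase that inserts sequencing adapters into accessible DNA. Cells had been crosslinked, permeabilised and tagmented, and the material was passed over Q Sepharose, a strong anion exchanger that holds negatively charged complexes until salt releases them. The flow-through (FT) and the washes with 20, 100, 200, 300, 500, 700 and 1000 mM NaCl gave 8 libraries, named G20 to G1000 for the washes. The peaks of the G200 list carry the name G50_200, so whether it holds the 200 mM wash alone was not settled. Each fraction had 1 library and there were no replicates, so no difference below has a replicate check, and every test compares these libraries and not the conditions. The deposited data were 1 MACS2 peak list per library, and positions are hg19. The design text sets out to find how accessibility and transcription factor motifs change between fractions. Accessibility was compared here, and motifs were not analysed here.

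Accessible regions were found in all 8 fractions, from the flow-through to the highest salt. FT held 22807 peaks, G20 held 19484, G100 held 13244, G200 held 15988, G300 held 19717, G500 held 10384, G700 held 8102 and G1000 held 10246. The peaks covered between 3.76 Mb in G700 and 13.5 Mb in FT. Their median width was 527 bp in FT, 460 bp in G20, 462 bp in G100, 477 bp in G200, 488 bp in G300, 450 bp in G500, 418 bp in G700 and 443 bp in G1000. The depth behind the lists differed as well. The background recovered from the peak statistics was 2.36 reads per kb in FT, 1.62 in G20, 1.12 in G100, 0.817 in G200, 1.73 in G300, 0.972 in G500, 0.917 in G700 and 1.03 in G1000. G200 had the lowest background and still the fourth-longest list.

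**Figure D1:**
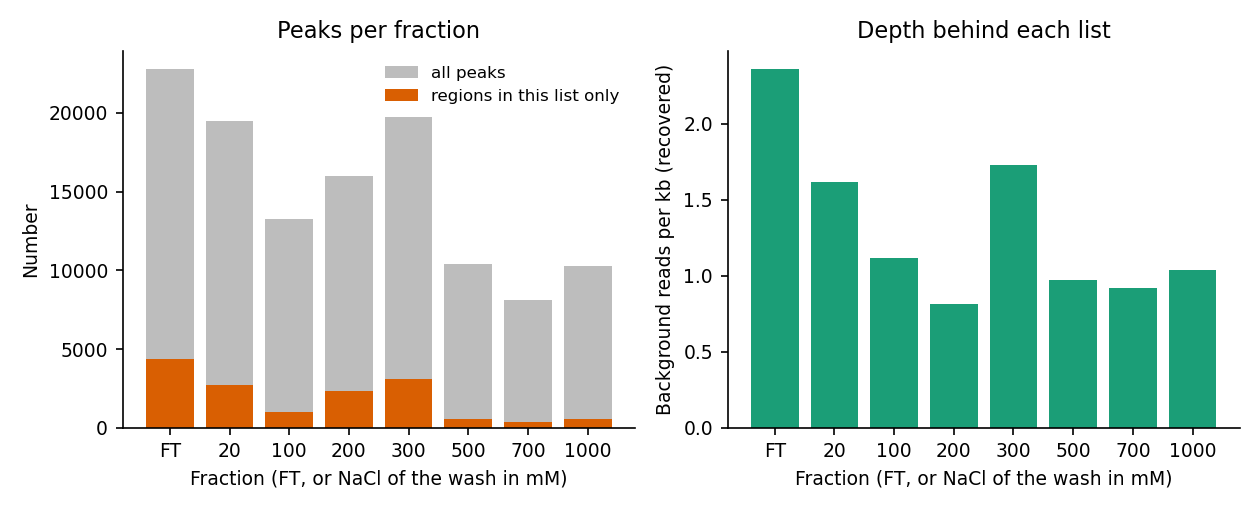
Number of peaks in each fraction, with the regions found in that list only (left), and background reads per kb recovered from the peak statistics (right), for FT and for the washes by NaCl concentration in mM, 1 library each. FT had both the most peaks (22807) and the highest background (2.36 reads per kb), while G200 had 15988 peaks at the lowest background (0.817).

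The strongest peaks of the fractions lay in the same places. The peak with the highest −log10 q of each list lay on chromosome 1 within 121484125 to 121485442, directly before the longest peak-free stretch of that chromosome, which holds the centromere. Its −log10 q, the authors' value, ran from 1254 in G200 to 2701 in FT. The second was on chromosome 19 within 27731858 to 27732782, at the other edge of such a stretch, in 7 of the lists. In G200 it was instead on chromosome 1 from 564701 to 565278, with a −log10 q of 637. Of the 10 regions shared by all lists with the highest mean rank, 7 lay within 1 Mb of the longest peak-free stretch of their chromosome, among them chromosome 7 from 61968664 to 61969772, chromosome 10 from 42529202 to 42529841 and chromosome 2 from 92324329 to 92325583. The other 3 were on chromosome 3 from 73159863 to 73160332, on chromosome 9 from 69710737 to 69711340, and on an unplaced chromosome 9 sequence. Peaks beside centromeres commonly hold satellite repeats, whose copies the assembly collapses.

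A core of accessible regions was shared by all fractions. Merging the 8 lists gave 36845 regions, of which 4241 (11.5%) were called in all 8 lists and 15013 (40.7%) in a single list. Regions of a single list were weak: in FT their median −log10 q was 3.28, against 15.0 for peaks in regions of all 8 lists, and in G700 it was 2.49 against 6.95. Between 31.7% and 89.8% of the peaks of a list overlapped a peak of another list by at least 1 bp, against 0.315% to 0.898% for peaks shuffled within chromosomes. With each list reduced to its 8102 peaks of highest −log10 q, the overlap was 61.8% to 74.7% for every pair, and 3027 regions were in all 8 lists. The summits agreed less closely: 4181 peaks of G700 (51.6%) met a peak in each of the other 7 lists by 1 bp, and 663 (8.18%) had a summit within 100 bp in each.

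Fractions next to each other in salt were not measurably more alike than distant ones. Over the 7 salt libraries, Spearman's rho between the Jaccard index of 2 lists and their distance in salt steps was −0.32 (exact permutation p = 0.135, two-sided) with all peaks and −0.04 (exact permutation p = 0.885) at equal list length. With FT placed before G20, an alternative added after the data were seen, it was −0.43 (exact permutation p = 0.0272) with all peaks and −0.20 (exact permutation p = 0.346) at equal list length. Without G200, whose place in the salt order was not settled, rho was −0.38 (exact permutation p = 0.131) with all peaks. It was 0.04 (exact permutation p = 0.906) at equal list length without G200. The similarity test was not among those fixed before the data were examined. A trend of peak width with salt did not pass the test: over the 7 salt libraries rho was −0.61 (exact permutation p = 0.167) and Pearson's r was −0.63 (exact permutation p = 0.132). Without the 2 libraries farthest from the median salt, r was −0.11. With FT added by rank, rho was −0.74 (exact permutation p = 0.0458). Of the 30 trends with salt that were tested over the 7 libraries, 0 passed after Benjamini-Hochberg adjustment, 3 had an unadjusted exact permutation p under 0.05, and the smallest adjusted p of the exact permutation tests of rho was 0.330. Chromosome 7 had the smallest unadjusted value, with rho 0.86 (exact permutation p = 0.0238).

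Regions called on the low-salt side alone far outnumbered those called on the high-salt side alone when all peaks were used. The low side was FT, G20 and G100, and the high side was G500, G700 and G1000. There were 1143 regions called in all 3 low-side lists and no high-side list, against 2 of the reverse. Each low-side library also had a higher recovered background than each high-side library. It was at least 1.12 reads per kb (G100) on the low side and at most 1.03 (G1000) on the high side. At equal list length the counts were 129 and 79. The low-side regions were weak in the lists that called them, with a median −log10 q of 4.94 in the low-side lists against 13.6 for regions of all 8 lists. Many reached into the middle fractions: 818 (71.6%) were called in G300 and 635 (55.6%) in G200. The 12 low-side regions with the highest mean rank included chromosome 14 from 74226765 to 74227480, with −log10 q of 13.3 in FT, 22.2 in G20 and 12.2 in G100, and chromosome 17 from 79212708 to 79213347, with 19.2, 13.3 and 12.3. Among the others were chromosome 7 from 83306522 to 83307171, chromosome 1 from 28585682 to 28586410, and 3 regions on chromosome 19, such as 46272522 to 46272938. Of these 12, 11 were also called in G200 and 10 in G300. The 2 high-side regions were chromosome X from 133887250 to 133887886, with −log10 q of 6.09 in G500, 3.16 in G700 and 4.02 in G1000, and chromosome 8 from 30580297 to 30581062, with 3.31, 2.03 and 1.81, and both were also called in G300. Other groupings of the same 6 libraries into 3 and 3 gave up to 587 regions with all peaks (FT, G20 and G500) and up to 128 at equal list length (FT, G20 and G1000). There are only 10 such splits, so no share under 0.1 can be reached.

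**Figure D2:**
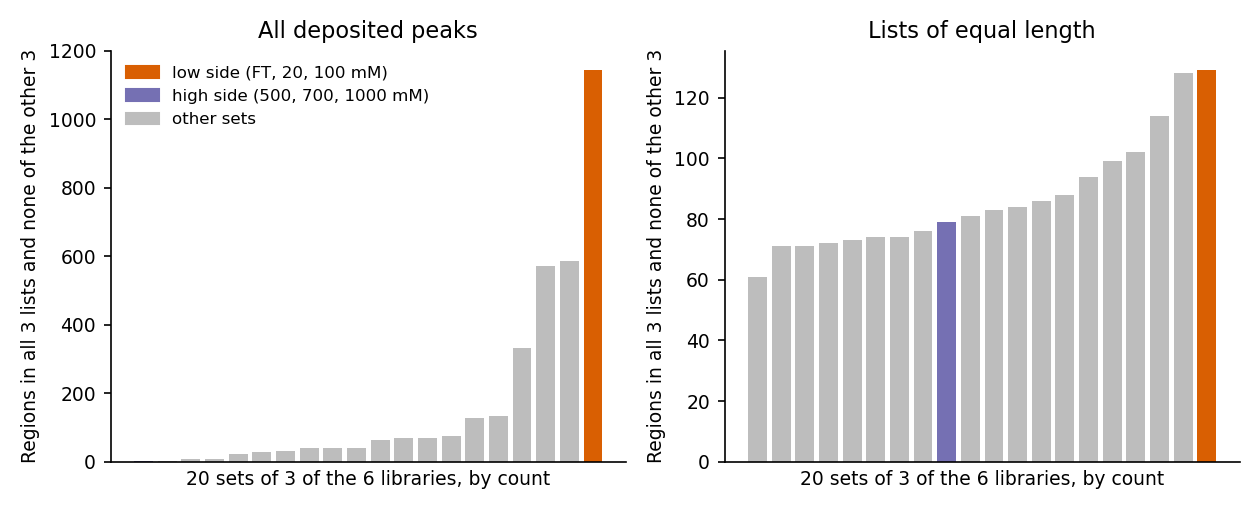
Number of regions called in all 3 lists of a set and in none of the other 3, for the 20 sets of 3 that 6 libraries form (FT, G20, G100, G500, G700 and G1000), ordered by count, with all deposited peaks (left) and with 8102 peaks per list (right). The low-side set stands at 1143 and the high-side set at 2 with all peaks, and at 129 and 79 at equal list length.

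Low-side regions lay more often on chromosome 17. It held 69 of the 1143 (6.04%) against 309 of the 8647 other regions called in all 3 low-side lists (3.57%; odds ratio 1.73, Fisher's exact test, adjusted p = 0.00331). At equal list length it held 13 of 129 (10.1%) against 178 of 4762 (3.74%; odds ratio 2.89, Fisher's exact test, adjusted p = 0.0329). Chromosome 15 was higher with all peaks (4.29% against 2.72%, adjusted p = 0.0361 in Fisher's exact test) and chromosome 6 was lower (4.81% against 7.70%, adjusted p = 0.00331 in Fisher's exact test). At equal list length chromosome 15 kept its direction (5.43% against 2.35%, odds ratio 2.38, adjusted p = 0.202 in Fisher's exact test over 23 chromosomes). Chromosome 6 turned its direction there (10.9% against 7.03%, odds ratio 1.61 beside 0.606 with all peaks, adjusted p = 0.441 in Fisher's exact test). Regions are not replicates, so these tests describe the 2 sets of regions only. They were not among the tests fixed before the data were examined.

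At equal list length chromosomes 17, 19 and 22 held their smallest shares in the G700 list, on chromosome 22 together with G500, and their largest in FT, G20 and G200. Chromosome 19 held 6.46% of the peaks of FT (95% Clopper-Pearson interval 5.93 to 7.01), 6.32% of G20 (5.80 to 6.87) and 6.70% of G200 (6.17 to 7.27), against 4.88% of G700 (4.42 to 5.37) and between 5.26% (G500) and 5.74% (G300) of the other 4 lists. Chromosome 17 held 4.62% of FT and 4.81% of G200, against 3.14% of G700, and between 3.48% (G500) and 3.65% (G300) of G100, G300, G500 and G1000. Fisher's exact test of FT against G700, a pair set after the data were seen, gave an adjusted p of 0.000356 for chromosome 19, 5.48e-05 for chromosome 17 and 0.0103 for chromosome 22, over 46 tests. The other pair among these tests, G200 against G300, gave an adjusted p of 0.00429 for chromosome 17, 0.0723 for chromosome 19 and 0.233 for chromosome 22 (Fisher's exact test). At equal length the lowest −log10 q kept was 7.89 in FT and 1.32 in G700, so FT and G700 also differed in the strength of the peaks compared. With all peaks the direction turned for chromosome 19 in FT and G20, which held 4.52% and 4.60%, against 4.84% in G500, 4.88% in G700 and 4.94% in G1000. Chromosomes 4 and 13 went the other way, and chromosome 4 held 4.30% of FT and 5.23% of G700 (adjusted p = 0.0433 in Fisher's exact test).

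The reads over each summit could be recovered from the deposited fold enrichment and p-value, and they allowed the same regions to be compared across libraries. Of the 4241 regions called in all 8 lists, 4220 had a recovered read number in each. After scaling to the reads in 4091 ordinary regions (placed chromosomes, away from ends and from the longest peak-free stretches), 100 regions (2.37%) differed between 1 library and the other 7 (exact binomial test, two-sided, Benjamini-Hochberg adjusted over regions and libraries). G200 was higher in 27 and lower in 48, and FT was higher in 23 and lower in 13. Each of the other 6 libraries had between 9 and 17 such regions. Without G200 the count was 43, and without FT and G200 it was 16. A separate test of ordinary regions alone called 30 with all 8 libraries and 1 without FT and G200. For the 15 pairs of libraries that include neither, the spread of the reads over ordinary regions was 0.663 to 0.879 times that of counting alone. For pairs with G200 it was 1.37 to 1.83 times, and for FT with the remaining libraries 1.07 to 1.31 times. Values below 1 mean less spread than the counting model gives, so its intervals and tests are approximate here. The cause was not tested. Scaled to each library's background instead, 1212 regions differed.

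Copies of ribosomal DNA were among the regions that differed. Of the 100, 53 were ordinary regions, 23 lay beside the longest peak-free stretches, 13 on other unplaced or random sequences, 8 on the unplaced scaffold gl000220 and 3 at chromosome ends. The scaffold gl000220 carries copies of the ribosomal RNA genes, and 10 of its regions were called in all 8 lists. Their reads were 2.18 times the expected number in G200 (95% Poisson interval 2.12 to 2.24, counting error only) and 1.30 times in FT (1.26 to 1.34), against 0.822 in G20, 0.742 in G100, 0.641 in G300, 0.801 in G500, 0.604 in G700 and 0.674 in G1000. Set against the other 7 libraries together, G200 had 2.62 times the expected reads and FT had 1.38 times. With background scaling G200 stayed above the other 7 libraries together (4.45 times), and FT did not (0.990 times). The largest of these regions by reads, from 116972 to 118393, had 2.42 times the expected reads in G200, 1.31 times in FT, 0.854 in G20 and 0.599 in G700. On chromosome 21 the region from 9826754 to 9827559 had 2.53 times the expected reads in G200 and 0.650 times in G700, while the 1.20 times of FT was not called (adjusted p = 0.0964 in the exact binomial test). These regions, and those in the next paragraph, were picked after their values were seen.

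Regions within 1 Mb of the longest peak-free stretch numbered 73. With expected shares from ordinary regions, they had 0.657 times the expected reads in G200 (0.634 to 0.680) and 0.883 to 1.17 times in the other libraries. Set against the other 7 libraries together, the G200 value was 0.626, and with background scaling it was instead 1.06. The 7 regions within 20 kb of a chromosome's first base or of its last peak, near the telomere repeats, had 0.648 times the expected reads in FT (0.575 to 0.728), 1.29 times in G100 (1.17 to 1.43) and 1.53 times in G500 (1.38 to 1.70). On chromosome 5 from 10058 to 11759, FT had 0.429 times the expected reads, G100 had 1.46 times and G500 had 1.66 times, while the 1.23 times of G300 was not called (adjusted p = 0.681 in the exact binomial test).

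**Figure D3:**
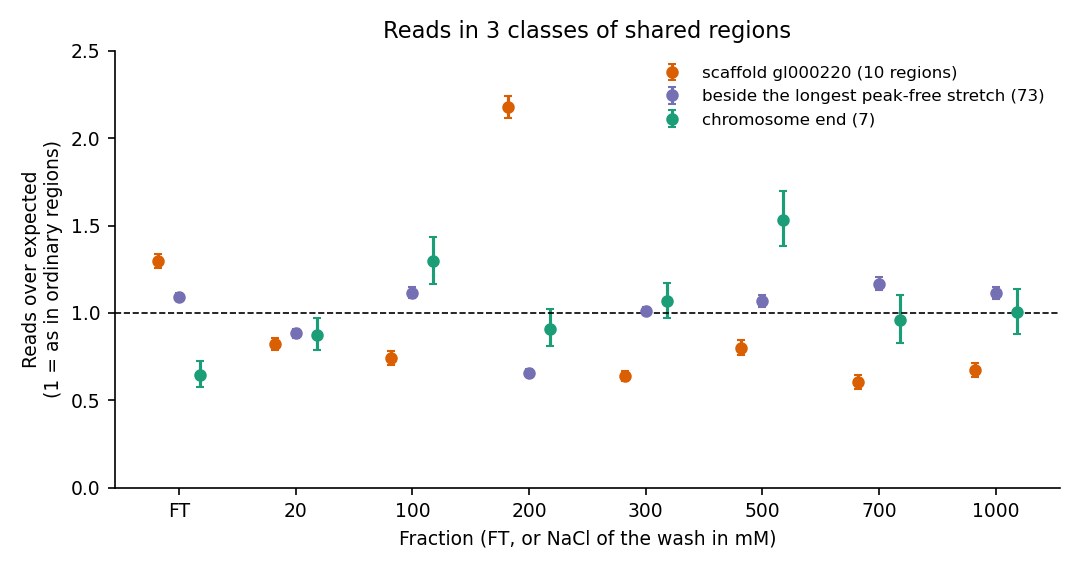
Reads over the expected number (y axis) in 3 classes of regions called in all 8 lists, for FT and the washes by NaCl in mM. A value of 1 means that a library's share of the reads of the 8 libraries equals its share in ordinary regions. Bars are 95% Poisson intervals for counting error. The 10 regions of scaffold gl000220 reach 2.18 in G200 and 1.30 in FT, and lie between 0.604 and 0.822 in the other 6 libraries.

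Low-side and high-side libraries differed in 14 of the 4220 shared regions when their reads were summed (exact binomial test, two-sided, adjusted). Reads were higher on the low side in 11 and on the high side in 3, and 185 regions (4.38%) had an unadjusted p under 0.05. With background scaling the balance turned, with 8 higher on the low side and 17 on the high side. Those higher on the low side were 8 on gl000220, 2 on chromosome 21, from 9825598 to 9826406 and from 9826754 to 9827559, and chromosome 3 from 73159863 to 73160332. Over the expected number, the reads of the last were 1.42 times in FT, 0.972 in G20 and 0.716 in G100, against 0.843 in G500, 0.895 in G700 and 0.815 in G1000, so of these 6 only FT was raised. Those higher on the high side were chromosome 1 from 566064 to 566755, the end of chromosome 5 named above, and chromosome 7 from 137686143 to 137687490, with 1.29 times the expected reads in G500, 1.30 in G700 and 1.35 in G1000, against 0.478 in FT, 1.11 in G20 and 0.891 in G100. Without FT, 1 region was higher on the low side, and without G100, 9 were higher on the high side. Of the 4091 ordinary regions, 2 were higher and 1 was lower on the low side when tested alone.

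Within ordinary shared regions, the reads of G200 and FT were spread unevenly over the chromosomes. The chromosomes named here were picked after their values were seen. G200 had its highest ratio on chromosome 21, with 1.35 times the expected reads (95% Poisson interval 1.28 to 1.42), and FT had 1.11 times there (1.06 to 1.17). The 2 regions of chromosome 21 named above are among its 34 ordinary regions, and without them, an alternative added after the data were seen, the ratio was 1.02 in both G200 and FT, with 95% Poisson intervals that include 1. Chromosomes 17, 19 and 22 together had 1.21 times the expected reads in G200 (95% Poisson interval 1.19 to 1.23), 1.07 times in FT (1.05 to 1.09) and 1.02 times in G20 (1.00 to 1.04). The other libraries had 0.927 in G100, 0.926 in G300, 0.924 in G500, 0.901 in G700 and 0.934 in G1000. G200 also had 1.12 times the expected reads on chromosome 16, 1.11 on chromosome 20 and 1.09 on chromosome 10. On chromosome 4 the ratio was 0.920 in G200 and 0.936 in FT, against 1.09 in G700. G200 also had the highest reads over background in ordinary shared regions, with a mean of 93.7 times the background, against 68.5 in G20, 62.3 in G100, 60.6 in G500, 59.4 in G300, 59.2 in G1000, 58.0 in G700 and 46.4 in FT.

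**Figure D4:**
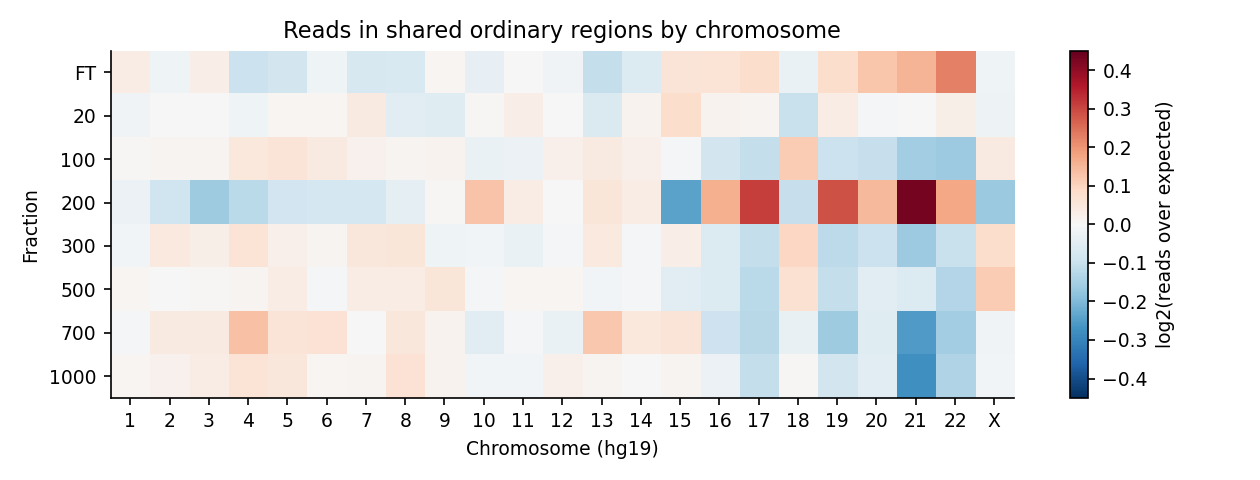
Reads over the expected number, as log2, in ordinary regions called in all 8 lists, by chromosome (x axis, hg19) and fraction (y axis, FT and NaCl in mM); red is above and blue below the expected number. G200 is above on chromosomes 21 (1.35 times), 17 (1.24 times) and 19 (1.22 times), and FT on chromosome 22 (1.17 times).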

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

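Of the tests of explanations in this part, the counts at equal list length had been planned before the data were examined, and the bound set on them and all other tests were chosen after the results were seen. Each of 58 measures was compared over the 8 libraries, and a library was singled out where its gap to the nearest other was large for the whole range (Dixon's test). This happened 10 times, where chance gives about 1 in 20, or 2.9. The measures overlap, and some were picked after their values were seen, such as the chromosome 1 region and scaffold gl000220. The chance number does not hold for such measures. G200 was the library singled out in 9 of the 10. It had 19580 peaks per background read per kb against 12057 in G20, the next. Its mean reads over background in ordinary shared regions were 93.7 times against 68.5 in G20. In the chromosome 1 region that starts at 566064, its reads were 4355 times its background against 677 in G1000. On scaffold gl000220 it had 2.18 times the expected reads against 1.30 in FT. By chromosome, its relative reads were 0.895 on chromosome 3, 1.09 on chromosome 10, 0.845 on chromosome 15 and 1.24 on chromosome 17, and chromosome 10 held 4.54% of its peaks at equal list length against 4.15% in G500. G700, the shortest list, had the lowest mean Jaccard index with the other lists, at 0.303 against 0.346 in FT.

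The G200 library stood apart in ribosomal DNA, in reads over background and in its reads on some chromosomes. Lower depth was weighed with G700, the nearest to G200 in recovered background. G700 had 58.0 reads over background, and G200 had 1.62 times that, which argues against lower depth if the lists share their peak calling settings. Those settings are not given. The background enters both the depth and the reads over background, so a setting particular to G200 would change both. A gradual change along the salt steps was not seen on gl000220, where both neighbours of G200 lay below the next library outward. G100 had 0.742 times the expected reads (0.705 to 0.780) against 0.822 in G20, and G300 had 0.641 times against 0.801 in G500. The expected number pools the 8 libraries, so a high G200 lowers the others, and values below 1 alone decide nothing. Each value is from 1 library, with counting error only. Separate processing that kept repeated sequence may account for the ribosomal and chromosome 1 reads, and the list's own names and number format differ from the others. Regions beside the longest peak-free stretches, a class set by position and not by repeat annotation, had 0.657 times the expected reads in G200. Relative to the other 7 libraries, G200 had 0.626 times the reads there, and 1.06 times with background scaling, so this stays open. Also open, and not tested, are a list from another run, a pooled 50 to 200 mM fraction, as the peak name G50_200 reads, and chromatin released only near 200 mM. Until this is known, no G200 value can be tied to the 200 mM wash alone.

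The surplus of low-side regions may come from the longer lists of those libraries. At equal list length the count was 129, beside 128 for the highest other set of 3, and 79 on the high side. For all peaks, the difference between the sides was 1141 in the real split and at most 578 in the others, and 1 of 10 splits was as large, the real one. For the summed reads, the real split called 14 regions and 4 of 10 splits called at least as many, with up to 21. With 10 splits no share can fall under 0.05. Depth differed between the sides as well. The background reads per kb summed to 5.09 on the low side, the highest of all sets of 3. On the high side they summed to 2.92, the lowest. Depth and list length therefore cannot be told apart here. What stays open is whether list length itself reflects how much open chromatin a fraction held, which was not tested.

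Chromosomes 17, 19 and 22, picked after the values were seen, had more reads in FT and G200. Depth, taken as the recovered background, is argued against if the lists share their peak calling settings. The 4 libraries nearest to G200 in depth had 0.901 (G700, 0.878 to 0.925) to 0.934 times the expected reads on these chromosomes. This is below the 1.02 of the deeper G20. List length did not order these ratios: G300, with 19717 peaks, had 0.926 times the expected reads, against 1.21 in G200 with 15988 peaks. FT, with the longest list, had 1.07 times. Longer lists or weaker peaks stay open, since the lowest 95% bound of the 6 ratios, 1.02, comes from the chromosomes picked for these ratios and excludes nothing. Base composition could play a part, but it was not measured, and the 0.920 times of G200 on chromosome 4 does not test it. Chromosome 21, which had 1.35 times in G200, had 1.02 times without its 2 regions whose reads differed. Without a genome sequence, composition cannot be told apart from a difference in the chromatin that each fraction held.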

How the results depend on the processing

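The alternatives for the peak lists, peak width and the low-side and high-side regions were fixed before the data were examined, as were part of those for shared regions and list similarity. Added after the data were seen were list similarity with FT added or without G200, shared regions with libraries left out, and all alternatives for recovered reads. These outnumbered the alternatives fixed before. The count of regions in all 8 lists (4241) fell to 2287 at −log10 q of at least 5, and was 4249 to 5252 without each library in turn. The G700 peaks met in the other lists (4181 by 1 bp) numbered 2386 with a reciprocal overlap of at least 50% and 663 with summits within 100 bp. Adding FT by rank gave rho −0.43 (exact permutation p = 0.0272) for list similarity and −0.74 (exact permutation p = 0.0458) for peak width. Width kept its direction without each library in turn (−0.71 to −0.37) and passed no threshold there. Low-side regions (1143) were 129 at equal list length, 4576 with calls in 2 of 3 lists, and 1507 to 3481 without each library, where fewer lists are required; high-side regions (2) were 79, 62 and 5 to 30, with 7 in 200 bp windows and 0 at −log10 q of at least 5. Regions whose reads differed (100) were 43 to 102 without each library, the lowest without G200, 16 without FT and G200, 30 in ordinary regions alone and 1212 with background scaling. Regions higher on the low side (11) were 1 (without FT) to 12 without each library, 2 in ordinary regions and 8 with background scaling; those higher on the high side (3) were 2 to 9 (without G100), 1 in ordinary regions and 17 with background scaling, so 11 against 3 became 8 against 17. Relative to the other 7 libraries, FT on gl000220 went from 1.38 to 0.990 with background scaling, and G200 beside peak-free stretches from 0.626 to 1.06. Without the regions whose reads differed, G200 went from 0.930 to 1.01 on chromosome 18, which turned its direction, and from 1.35 to 1.02 on chromosome 21, while chromosomes 17, 19 and 22 kept theirs in FT and G200. Where the setting does not itself require fewer lists or peaks, the cause was not tested. Counting each summit changed nothing, as 0 intervals were repeated. Promoter, GC, motif and gene list alternatives were not run. A rise of 2 times in 1 library was called in 45.5% of simulated regions, so smaller differences would mostly be missed in such draws. The draws had 0.995 times the spread of counting alone, against 0.663 to 0.879 for the 15 real pairs without FT and G200. The share detectable in the real data may therefore differ.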

Other observations

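A stretch near the start of chromosome 1, which resembles mitochondrial DNA, was called in each list, with very uneven reads. Whether reads of mitochondrial DNA were placed there was not tested. The peak starting within 566064 to 566075 had 4.22 times the expected reads in G200, 1.04 in G1000, 0.924 in G500, 0.626 in G700, 0.467 in G20, 0.434 in G100, 0.415 in G300 and 0.272 in FT. It had 1042 unscaled reads in G200 and 197 in G1000, the next highest. The expected number pools the 8 libraries, so the high G200 count lowers the ratios of the others. A second peak, from 564701 to 565278 in G200, had 1084 unscaled reads there and 164 in G20, and was not called in the other 6 lists. No peak was listed on the mitochondrial chromosome in any of the 8 lists.

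Regions of a single list were most numerous in FT (4360), followed by G300 (3109), G20 (2694), G200 (2345), G100 (1023), G1000 (568), G500 (565) and G700 (349). At equal list length the order turned: G700 had 1081, G500 807, G200 774, G1000 764, G100 598, FT 456, G300 411 and G20 392. The lowest −log10 q kept there was 1.32 in G700 and 7.89 in FT, so weak peaks stayed in G700 and left FT. Regions of a single list were weak, so this order cannot be read as a difference between fractions. Some regions had fewer reads in FT than expected, such as chromosome 12 from 133841529 to 133841891, with 0.478 times in FT, 1.01 in G20 and 1.87 in G500. Others had more, such as chromosome 9 from 131872780 to 131873890, with 1.82 times in FT, while the 0.564 of G20 and the 1.22 of G500 were not called.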
